A study of Mus musculus with 12 samples.

How the data were processed

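RNA was measured in 12 samples of cells sorted as beta cells from mice with green fluorescent protein under the Pdx1 promoter. Per the labels' protocols, islets were dissociated with trypsin, fluorescent cells were sorted, and biotin-labelled copies of the RNA were made with an Illumina amplification kit. Sample titles gave the age and the replicate number. Samples fell into E18.5 (4), P1 (3), P10 (2) and adult (3). The values used were the intensity of 25697 probes per array as deposited by the authors, on a linear scale. Any scaling or background subtraction by the authors, and the scanner software, are not given in the sources used here. The column medians lay between 39.1 and 43.4 and the smallest values between 25.3 and 29.3, and the values were treated as still holding background. A second table with 24 columns, holding a signal and a detection p for each of its arrays, was not used, because its column names match no sample.

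The design written before the data were examined assumed detection p-values for the background correction and the filter. Without them, background was estimated from the signals alone. The normexp model with an offset of 16 was fitted to each array, followed by quantile normalization and log2. A probe counted as above background on an array when it exceeded the limit set at a p of 0.01 from the mode of the signals and the spread below that mode. The limits lay between 39.7 and 48.6, and the mode rose with age, from a mean of 35.7 at E18.5 to 38.9 in adults. The share of probes above background averaged 45.5% at E18.5, 44.4% at P1, 44.6% at P10 and 41.0% in adults. Probes above background on at least 2 arrays were kept, 13205 in all. Gene names came from the platform table, in which 23978 probes had 1 symbol, 0 had several and 1719 are unnamed here. Gene IDs of 23962 probes were found in the RefSeq table, which served for names alone. No coordinates are printed, since no build is named. Per gene the probe with the highest mean was used, which left 9198 genes, 2367 of them with more than 1 kept probe. A gene counted as above background on an array when any of its probes did, kept or not. Such counts therefore need not concern the tested probe. Ins1 and Mki67 have no probe named here, some other fixed genes are not reported here, and Slc16a1, Hk1 and Pdgfra did not pass the filter. The highest share of probes with an identical value in a pair of samples was 0.95%, and all 12 samples were kept as separate.

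Genes were tested with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes on all 12 samples with age as the factor, and Benjamini-Hochberg adjustment with a threshold of 0.05. The moderated F-test covered all 4 ages, and 5 comparisons were made. These were P1 against E18.5, P10 against P1, adults against P10, adults against E18.5, and the means of both later against both earlier ages. In total 27 gene lists were fixed before the data were examined, and those with at least 5 measured genes were tested with fry, adjusted over the lists within a comparison. Fry tests whether the genes of a list move on balance in 1 direction, and does not compare the list with other genes. Camera, which compares a list with the other genes and so asks another question than fry, served as an alternative. It was run with an estimated correlation and with a preset correlation of 0.01. Counts adjusted over the list alone were computed from the same gene p-values. Where every sample of an age was below background, the fold is given as "at least", against the mean of the lowest level above background on each array of that age or the probe's own level if higher. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

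The genes to be named were set by a rule written before the data were examined. It took, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, leaving out clone-like names. It added 25 fixed genes, and from each list the 4 genes with the smallest p and the gene with the brightest probe, which does not rank abundance between genes. The text names part of these, taken in order of size or of p, and every gene the rule took was carried through the alternatives. The list of ATF4 targets in the closing section was drawn up after the values of several were seen. Genes named outside the rule are marked as chosen after their values were seen, apart from Arntl, a member of the clock list, whose value was looked at once the test on it had been written.

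Alternatives were other background corrections and scalings, other probe filters, the mean of a gene's probes, eBayes with trend and robust settings, array weights, the replicate number as a block, only the ages compared, a minimum of 2-fold, and each sample left out in turn. The mean of the acinar markers as an added term was chosen after seeing the data. The fit was tested on simulated data with 200 of 9198 genes changed. Changes of 1 log2 unit were recovered in 89.6% of cases for P1 against E18.5, 88.1% for P10 against P1, 80.6% for adults against P10, 88.1% for adults against E18.5 and 97.0% for the pooled comparison. Changes of 0.5 were recovered in 35.8%, 23.9%, 19.4%, 37.3% and 67.2% of cases, in the same order. False calls made up between 3.65% and 6.42% of all calls. For P10 against P1, 4 of 4 shifted lists were recovered with 0 false lists. The simulated genes varied independently of each other, so these results do not cover genes or lists whose members vary together. The number of arrays limits the precision.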

Results

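RNA levels were measured in 12 samples of mouse cells sorted as pancreatic beta cells, the islet cells that make insulin. The cells carried green fluorescent protein under the promoter of Pdx1, a transcription factor of the pancreas, and were sorted by that fluorescence from dissociated islets. The embryonic stage E18.5, shortly before birth, had 4 samples, postnatal day 1 (P1) had 3, postnatal day 10 (P10) had 2 and adults of 5 weeks had 3. Each sample was hybridised to 1 Illumina expression array, and between 40.0% and 48.3% of the probes lay above background on an array. Markers of alpha, delta, PP and epsilon cells, other cells of the islet, averaged log2 levels from 8.24 in adult replicate 3 to 10.50 in E18.5 replicate 2. Differences between ages are therefore those of the sorted samples and need not lie within beta cells. Within an age, samples correlated across genes with r from 0.977 to 0.991, although genes are not independent replicates. Samples of different ages reached r of 0.981, so the ranges overlap. The labels do not say whether samples came from separate litters, so p-values measure only the spread between these samples. The number of arrays limits the precision. Differences are in log2 units ± standard error, and adjusted p-values come from limma.

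The design asks how gene expression changes while beta cells acquire the function of adult beta cells. Ins2, which encodes insulin, was near the top of the array's range at every age, with mean log2 levels of 13.46 at E18.5, 13.59 at P1, 13.54 at P10 and 13.52 in adults. No comparison called it, and a change could be hidden at that end of the range. Among the 9198 genes tested, 4039 differed between at least some of the 4 ages by the moderated F-test. The bar chart of counts by comparison gives these by direction.

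**Figure D1:**
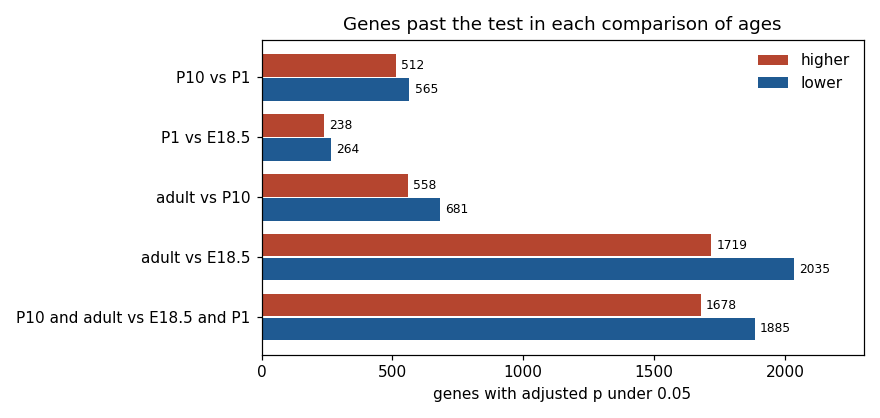
Horizontal bars give the number of genes with an adjusted p under 0.05 in each of the 5 comparisons of ages, out of 9198 tested, with genes higher and lower in the first-named age drawn separately. Adults against E18.5 had 1719 higher and 2035 lower genes, and P1 against E18.5 had 238 and 264.

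Around birth, from E18.5 to P1, Arrdc4, an arrestin-family gene induced by glucose, rose most, by 1.68 ± 0.22 or 3.21-fold (adjusted p = 0.0031, 3 P1 and 4 E18.5 samples). Next came Rgs16, a regulator of G protein signalling, at 2.80-fold, the phosphatase gene Dusp26 at 2.70-fold, and Fabp3, a fatty acid binding protein, at 2.61-fold. Cirbp and Rbm3, which encode RNA-binding proteins induced by cold, rose 2.60-fold and 2.38-fold. Dbp, a transcription factor driven by the circadian clock, rose 2.59-fold, and Txnip, a thioredoxin inhibitor induced by glucose, rose 2.34-fold. Olfr788 at 2.49-fold, above background in 3 of 4 E18.5 samples, and Haghl at 2.46-fold completed the 10 largest rises. Uhrf1, which maintains DNA methylation at replication, fell by 1.46 ± 0.29 on the log2 scale (adjusted p = 0.011). Cox6a2, a subunit of cytochrome c oxidase, was 2.53-fold lower, and the histone gene H2ac21 and the endoplasmic reticulum gene Creld2 were each 2.49-fold lower. Among the remaining large falls, the helicase gene Mcm5 was 2.42-fold lower, the nucleotide receptor gene P2ry1 2.39-fold, the replication kinase gene Cdc7 2.30-fold, Mcm10 2.26-fold, Tcf19 2.24-fold and Cdc6 2.23-fold. Several of these calls ended when 1 sample was left out, with differences of the same direction. Without P1 replicate 2 the adjusted p was 0.055 for Dusp26, 0.078 for Uhrf1, 0.076 for H2ac21 and 0.092 for Tcf19, and without P1 replicate 3 it was 0.059 for Tcf19. The Olfr788 call ended without any 1 of E18.5 replicates 1, 2 and 4, P1 replicates 1 and 2 or adult replicate 2, with adjusted p from 0.053 to 0.18. That of Cox6a2 ended without any 1 of E18.5 replicates 2, 3 and 4, P1 replicates 1, 2 and 3 or adult replicate 2, with adjusted p from 0.061 to 0.20.

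Of 31 measured cell cycle genes, 16 fell at P1, 0 rose and 15 did not pass the test, and 23 fell adjusted over the list alone. The thymidylate synthase gene Tyms was 2.17-fold lower, the helicase gene Mcm4 2.02-fold and the thymidine kinase gene Tk1 1.87-fold. The median of the list was -0.79 (adjusted p = 0.041 for the list by fry, and adjusted p = 0.32 by camera with an estimated correlation). Here and below, values with an estimated correlation come from camera. It compares a list with the other genes, which is another question than that of fry. Top2a, a topoisomerase of dividing cells, fell by 1.08 (adjusted p = 0.018), and its adjusted p was 0.054 without E18.5 replicate 4, 0.11 without P1 replicate 2 and 0.074 without P1 replicate 3. Of 18 genes of protein folding and stress in the endoplasmic reticulum, 5 fell and 13 did not pass, with 9 falling and 1 rising adjusted over the list alone. Hsp90b1, an endoplasmic reticulum chaperone, was 1.61-fold lower and the disulfide isomerase gene Pdia6 2.03-fold lower (median of the list -0.37, adjusted p = 0.041, and adjusted p = 0.32 with an estimated correlation). Of 12 circadian clock genes 5 rose and 7 did not pass, with 7 rising and 1 falling adjusted over the list alone, and the examples after Dbp were Tef at 1.94-fold and Per3, above background in 2 of 4 E18.5 samples, at 1.61-fold. Their median was 0.52 (adjusted p = 0.041, and adjusted p = 0.32 with an estimated correlation). The clock call ended with median centring (adjusted p = 0.098) and with the deposited values as log2 (adjusted p = 0.056). None of the 11 G1 cyclins and inhibitors passed the gene test, while adjusted over the list alone 5 fell and 1 rose. The list had a median of -0.31 (adjusted p = 0.041, and adjusted p = 0.32 with an estimated correlation). All 4 list calls ended without any 1 of E18.5 replicates 2, 3 and 4, P1 replicates 2 and 3 and P10 replicates 1 and 2, with adjusted p from 0.073 to 0.13 for the cell cycle list over these samples. The other lists also lost their call without P1 replicate 1. The clock list further lost it without adult replicate 1 (0.057 to 0.13 over its 9 samples), and the endoplasmic reticulum and G1 lists without adult replicate 2 (0.066 to 0.15 and 0.066 to 0.14). All 4 calls also ended with only both ages fitted and with the mean of the acinar markers as an added term. The endoplasmic reticulum and G1 calls ended without a filter on dim probes, and the G1 call with the mean of a gene's probes.

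At this step 0 of 25 acinar cell markers, which encode digestive enzymes of the exocrine pancreas, passed the gene test, by limma and adjusted over the list alone. Their median difference was 0.94 (adjusted p = 0.56 for the list). The insulin genes' regulators did not pass either, with Pdx1 at -0.10 ± 0.13, Mafa at -0.10 ± 0.22, Neurod1 at 0.09 ± 0.13 and Nkx6-1 at -0.27 ± 0.13. Ucn3, which encodes the peptide urocortin 3 of mature beta cells, stood at 0.45 ± 0.16 (adjusted p = 0.12). In all, 502 of 9198 genes passed, 238 higher and 264 lower. With median centring in place of quantile normalization the split was 149 higher and 349 lower, and with the deposited values as log2 it was 206 and 369. The number passing fell to 322 without E18.5 replicate 2, 320 without E18.5 replicate 3, 230 without E18.5 replicate 4, 114 without P1 replicate 2 and 282 without P1 replicate 3. It was 216 with the mean of the acinar markers as an added term, and 1010 with array weights.

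From P1 to P10, Dlk1, an imprinted gene of the fetal pancreas, fell by 4.27 ± 0.14 and was 19.3-fold lower (adjusted p = 1.6e-10, 2 P10 and 3 P1 samples). Ghrl, which encodes ghrelin, was 10.7-fold lower, and Npy, which encodes neuropeptide Y, 9.47-fold lower. Next came Lgi2 at 7.27-fold, Npas4, a transcription factor induced by calcium signals, at 7.04-fold, the sulfotransferase gene Chst8 at 6.34-fold and the imprinted gene Nnat at 5.37-fold. The amino acid transporter gene Slc38a5 was 5.35-fold lower, Gal, which encodes galanin and was above background in 1 of 2 P10 samples, 5.24-fold and Gp9 5.05-fold. Ucn3 rose by 2.67 ± 0.19 or 6.34-fold (adjusted p = 1.5e-06), and Iapp, the islet amyloid peptide secreted with insulin, by 1.23 ± 0.28 or 2.35-fold (adjusted p = 0.011). Without P10 replicate 1 the adjusted p of Iapp was 0.15. Nkx6-1, a transcription factor of beta cells, fell by 0.68 ± 0.16 (adjusted p = 0.011), with adjusted p of 0.084 without P10 replicate 1 and 0.070 without P10 replicate 2. The other regulators did not pass, with Pdx1 at 0.32 ± 0.16, Mafa at 0.21 ± 0.26 and Neurod1 at 0.31 ± 0.16. The glucose transporter gene Slc2a2 stood at 0.09 ± 0.18 and the phosphatase gene G6pc2 at 0.48 ± 0.24. Of the hormone genes of other islet cells, Ghrl fell as given above. Gcg at 0.78 ± 0.86, Sst at 0.11 ± 0.22 and Ppy at 1.44 ± 0.75 did not pass.

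Of the 25 acinar cell markers, 23 rose at P10 and 2 did not pass, with 24 rising adjusted over the list alone. Ctrl, a chymotrypsin-like protease, rose by 5.04 ± 0.53 or 32.8-fold (adjusted p = 2.9e-05), the secreted lectin gene Reg1 by 4.86, the trypsinogen gene Prss2 25.0-fold, the carboxypeptidase gene Cpb1 by 4.46 and the lipase gene Cel 20.8-fold. The trypsinogen gene Try10 rose 20.1-fold, with an adjusted p of 0.084 without P10 replicate 1. Prss2 and Cpb1 were above background in 2 of 3 P1 samples. The median of the list was 3.84 (adjusted p = 0.0077, adjusted p = 0.32 with an estimated correlation, and adjusted p = 0.063 without P10 replicate 1), and the mean level of the markers went from 6.28 to 9.79.

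In the same samples, 4 of 16 genes of glucose sensing and insulin production rose and 12 did not pass, also adjusted over the list alone. After Ucn3 these were led by the cation channel gene Trpm5 at 2.42-fold and the oxidoreductase gene Ero1b at 2.17-fold (median 0.13, adjusted p = 0.0077, and adjusted p = 0.32 with an estimated correlation). Of 23 genes of the secretory granule and exocytosis, 4 rose, 1 fell and 18 did not pass, with 6 rising adjusted over the list alone. Syt4, a synaptotagmin of secretory vesicles, rose by 2.28 ± 0.13 or 4.86-fold, and Stx1a, a syntaxin of the plasma membrane, fell by 1.47 ± 0.15 (median 0.09, adjusted p = 0.048, and adjusted p = 0.61 with an estimated correlation). Of 12 fetal growth and imprinted genes 6 fell and 6 did not pass, and adjusted over the list alone 8 fell and 1 rose. The RNA-binding protein gene Igf2bp3 was 3.14-fold lower and the growth inhibitor gene Grb10 4.12-fold lower (median -1.34, adjusted p = 1.4e-05, and adjusted p = 0.059 with an estimated correlation). The growth factor gene Igf2 stood at -1.52 ± 0.53 (adjusted p = 0.080). Of 40 ribosomal protein genes 9 fell and 31 did not pass, 10 falling adjusted over the list alone, with Rplp0 2.09-fold and Rpl28 1.73-fold lower (median -0.25, adjusted p = 0.013, and adjusted p = 0.32 with an estimated correlation). The ribosomal list was lost with median centring and with the deposited values as log2, and had an adjusted p of 0.060 and 0.067 without either P10 replicate. Of 8 duct cell markers 4 fell, 1 rose and 3 did not pass, and adjusted over the list alone 6 fell and 1 rose. The keratin gene Krt7 was 1.61-fold lower, and the member that rose was Tspan8, 3.42-fold, whose adjusted p was from 0.054 to 0.21 without any 1 of P1 replicates 1 and 2 and P10 replicates 1 and 2 (list median -0.56, adjusted p = 0.0077, and adjusted p = 0.32 with an estimated correlation). Without P10 replicate 1 the adjusted p of the glucose sensing and duct lists was 0.063. The exocytosis list lost its call without any 1 of 9 samples, with adjusted p from 0.061 to 0.36, and passed without E18.5 replicate 2, adult replicate 2 or adult replicate 3. It also lost its call with the deposited values as log2 and with array weights.

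In the same samples, of 11 endocrine progenitor genes 3 fell and 8 did not pass, also adjusted over the list alone, led by the growth arrest gene Gadd45a at 2.31-fold lower (adjusted p = 0.020, and adjusted p = 0.32 with an estimated correlation). Of 8 neuropeptides and peptide hormones 2 fell, namely Gal and Npy, 1 rose, namely Ucn3, and 5 did not pass, also adjusted over the list alone (adjusted p = 0.041, and adjusted p = 0.49 with an estimated correlation). Of 18 genes of antigen presentation and interferon response 1 rose, also adjusted over the list alone. This was Oasl2 at 0.59 ± 0.16, above background in 1 of 3 P1 samples, with an adjusted p of 0.066 without P1 replicate 1, 0.088 without P1 replicate 2 and 0.30 without P10 replicate 2. The list passed at an adjusted p of 0.048 (adjusted p = 0.49 with an estimated correlation) and lost its call in 23 of 26 other settings, among them without any 1 sample other than E18.5 replicate 2 (adjusted p from 0.053 to 0.24). Of 31 cell cycle genes 7 rose and 24 did not pass, with 9 rising adjusted over the list alone, and the list did not pass (median 0.39, adjusted p = 0.12). In all, 1077 genes passed, 512 higher and 565 lower. The number fell to 700 without P1 replicate 2, 392 without P10 replicate 1 and 517 without P10 replicate 2, and the 9 list calls to 1 without P10 replicate 1 and 4 without P10 replicate 2. The adjusted p of the progenitor list was from 0.056 to 0.11 without any 1 of P1 replicates 1 and 3 and P10 replicates 1 and 2. The neuropeptide list reached from 0.063 to 0.22 without any 1 of E18.5 replicate 3, P1 replicates 1 and 2 and P10 replicates 1 and 2, and did not pass without a filter on dim probes. With the mean of the acinar markers as an added term 52 genes and 1 list passed, and with only both ages fitted 1 list, in each case the fetal growth and imprinted list.

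**Figure D2:**
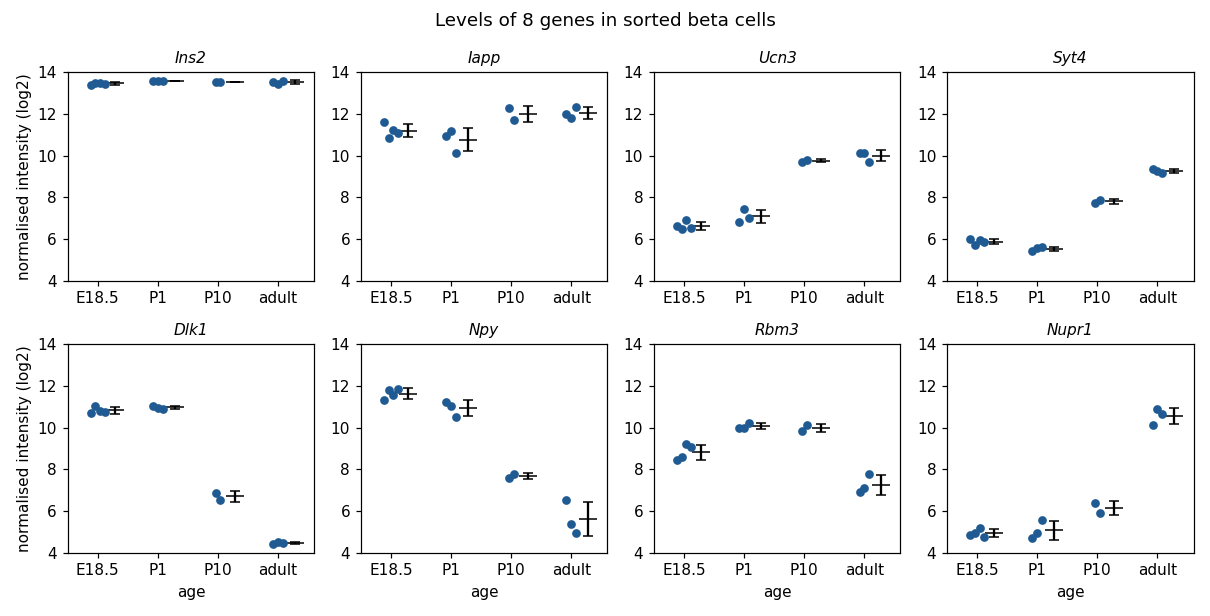
Each panel shows the normalised log2 intensity of 1 gene against age, with 1 dot per sample and a bar for the mean with its standard deviation (4 samples at E18.5, 3 at P1, 2 at P10 and 3 adults). Dlk1 and Npy fell between P1 and P10 and again by adulthood, Ucn3 rose between P1 and P10, and Nupr1 rose between P10 and adulthood.

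From P10 to 5 weeks, Nupr1, a transcriptional regulator induced by stress, rose by 4.41 ± 0.25 or 21.3-fold (adjusted p = 1.3e-07, 3 adult and 2 P10 samples). Chac1, an enzyme that degrades glutathione, rose 14.3-fold, Pdyn, which encodes the opioid precursor prodynorphin, 12.6-fold and Aldh1l2, a mitochondrial enzyme of folate metabolism, 8.70-fold. The phospholipase gene Pla2g1b rose 6.36-fold, the translation repressor gene Eif4ebp1 5.50-fold, Hapln4 5.18-fold, Serpina10 4.44-fold, the transcription factor gene Atf5 4.31-fold and Cox6a2 4.25-fold. Without P10 replicate 2 the adjusted p of Cox6a2 was 0.11. Nrep fell by 2.78 ± 0.15 and was 6.88-fold lower (adjusted p = 1.3e-07). Rbm3 was 6.66-fold lower, the centromeric histone gene Cenpa 6.20-fold, Uhrf1 5.91-fold, Mfng, a modifier of Notch, 5.74-fold and Oat, ornithine aminotransferase, 5.69-fold. The histone genes H2ac7 and H2ac15 were 5.52-fold and 4.95-fold lower, the mitotic kinase gene Pbk 5.35-fold and Mslnl 4.88-fold. Npy fell again, to a level 4.24-fold below that at P10. Of 3 adult samples Npy was above background in 2 and Mfng in 1. G6pc2 rose by 0.83 ± 0.24 (adjusted p = 0.032), with adjusted p from 0.050 to 0.20 without any 1 of P10 replicates 1 and 2 and adult replicates 1, 2 and 3. Ucn3 stood at 0.25 ± 0.19, Iapp at 0.06 ± 0.28, Pdx1 at -0.34 ± 0.16, Mafa at 0.14 ± 0.26 and Slc2a2 at 0.08 ± 0.18, and none of these passed.

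Of the 31 cell cycle genes 20 fell, 0 rose and 11 did not pass, with 27 falling adjusted over the list alone. Nusap1, a spindle protein gene, was 4.46-fold lower, Tk1 2.58-fold, Mcm5 3.81-fold and Top2a 3.31-fold (median -0.93, adjusted p = 0.0055, and adjusted p = 0.35 with an estimated correlation). Of 12 fetal growth and imprinted genes 5 fell and 7 did not pass, 7 falling adjusted over the list alone. Dlk1, above background at P10 but in no adult sample, was at least 3.26-fold lower, Igf2bp3 at least 2.33-fold and Nnat 4.82-fold (median -0.57, adjusted p = 0.00048, and adjusted p = 0.20 with an estimated correlation). Of 18 genes of folding and stress in the endoplasmic reticulum 7 rose and 11 did not pass, with 9 rising adjusted over the list alone. Pdia6 rose 1.91-fold and the chaperone gene Dnajb9 1.82-fold (median 0.56, adjusted p = 0.036, and adjusted p = 0.44 with an estimated correlation). Their adjusted p was 0.087 for Pdia6 without P10 replicate 2 and 0.062 for Dnajb9 without P10 replicate 1. Of the 25 acinar cell markers 4 rose, also adjusted over the list alone, and the list did not pass (median 0.41, adjusted p = 0.62). In all, 1239 genes passed, 558 higher and 681 lower, against 379 higher and 832 lower with median centring. The number was 647 without P10 replicate 1 and 513 without P10 replicate 2, and the 3 list calls became 1 without P10 replicate 1 and 7 without E18.5 replicate 4. The cell cycle list had an adjusted p of 0.063 without P10 replicate 1. The endoplasmic reticulum list had from 0.051 to 0.23 without any 1 of E18.5 replicates 1 and 3, P1 replicate 2, P10 replicates 1 and 2 and adult replicates 2 and 3, and its call also ended with the mean of the acinar markers as an added term, with which 1109 genes and 2 lists passed. With only both ages fitted all 3 list calls ended. Of 3 adult samples Nnat and Nusap1 were above background in 2 and Tk1 in 1.

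**Figure D3:**
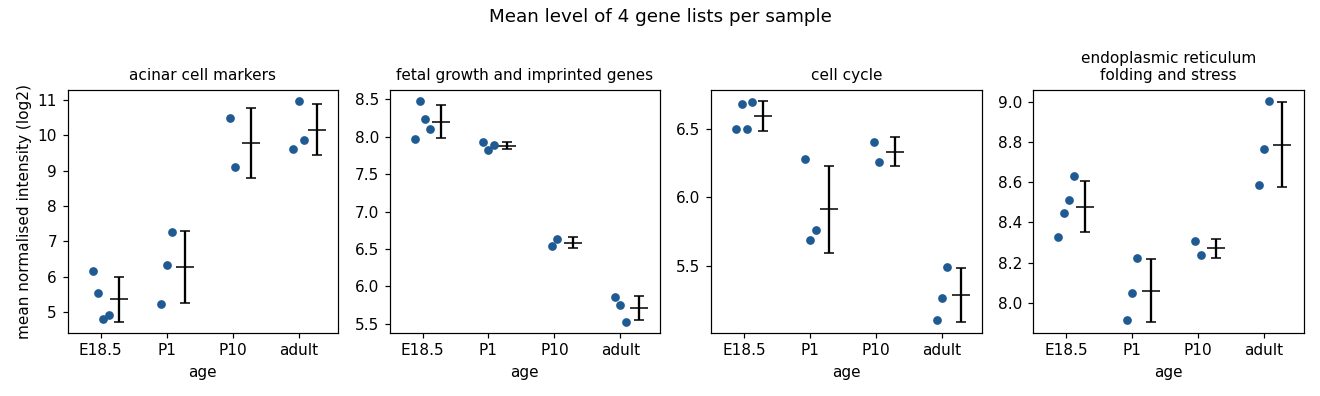
Each panel shows the mean normalised log2 intensity of the measured genes of 1 list against age, with 1 dot per sample and a bar for the mean with its standard deviation (4 samples at E18.5, 3 at P1, 2 at P10 and 3 adults); the vertical scales differ between panels. The acinar marker mean was 5.36 at E18.5 and 10.1 in adults.

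Between E18.5 and adults, the ends of the series, 3754 genes passed, 1719 higher and 2035 lower. Dlk1, below background in every adult sample, was at least 56.9-fold lower (adjusted p = 4.3e-14, 3 adult and 4 E18.5 samples). Npy was 65.1-fold lower, Ghrl at least 28.3-fold, Nnat 30.4-fold and Slc38a5 19.4-fold. The immediate early gene Egr4 was at least 12.5-fold lower, Mfng 14.3-fold, Nrep 12.4-fold, Igf2bp3 at least 8.13-fold and Grb10 10.9-fold. Igf2 was 6.22-fold lower. The lactate dehydrogenase gene Ldha was at least 1.84-fold lower. Ucn3 rose by 3.36 ± 0.16 or 10.3-fold, G6pc2 2.96-fold and Iapp 1.82-fold, the last with an adjusted p of 0.052 without adult replicate 3. Pdx1 at -0.12 ± 0.13, Mafa at 0.25 ± 0.22, Neurod1 at 0.12 ± 0.13 and Slc2a2 at 0.14 ± 0.15 did not pass. All 25 acinar cell markers rose, also adjusted over the list alone. Of 3 adult samples Npy and Nnat were above background in 2 and Mfng in 1. Try10 rose by 6.88 ± 0.70 or 118-fold, the trypsinogen gene Try4 87.2-fold, Ctrl 69.7-fold, the zymogen granule gene Zg16 68.0-fold and Prss2 61.4-fold (median 5.14, adjusted p = 0.00017, and adjusted p = 0.28 with an estimated correlation). At E18.5 Try10 was above background in 3 of 4 samples, and Try4, Ctrl, Zg16 and Prss2 in 2. With median centring the split was 1186 higher and 2655 lower, with the median of all genes at -0.12.

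Beside that rise of acinar markers, the fetal growth and imprinted list fell in 11 of 12 genes, and in 11 adjusted over the list alone (median -2.50, adjusted p = 2.9e-08, and adjusted p = 0.041 with an estimated correlation). It was the single list called here by fry that also passed by camera with an estimated correlation. Of 31 cell cycle genes 29 fell, also adjusted over the list alone, with Cenpa 10.1-fold, the survivin gene Birc5 3.99-fold and Nusap1 5.41-fold lower, Birc5 and Nusap1 being above background in 2 of 3 adult samples (adjusted p = 0.00017, and adjusted p = 0.28 with an estimated correlation). Of 12 genes reported as repressed in adult beta cells 10 fell, also adjusted over the list alone, led by Oat at 6.58-fold and the transglutaminase gene Tgm2 at 3.19-fold (mean -1.07, adjusted p = 0.00066, and adjusted p = 0.28 with an estimated correlation). In the same comparison the mean difference of the mesenchyme markers was -0.99 (adjusted p = 0.10 for the list) and that of the endothelial markers -0.94. In E18.5 replicates 1 to 4 the mean log2 level of the reported repressed genes was 6.17, 6.86, 6.56 and 6.13, that of the mesenchyme markers 4.81, 6.39, 6.15 and 5.04, and that of the endothelial markers 5.42, 7.05, 6.15 and 5.64. Of 16 genes of glucose sensing and insulin production 6 rose and 2 fell, also adjusted over the list alone, with Ero1b 2.69-fold higher and the granule effector gene Sytl4 down by 1.96-fold (adjusted p = 0.00050, and adjusted p = 0.37 with an estimated correlation). Of 23 granule and exocytosis genes 10 rose and 3 fell, with 10 and 4 adjusted over the list alone. Syt4 rose 10.5-fold, while Stx1a was 3.83-fold and the vesicle gene Vamp3 2.14-fold lower (adjusted p = 0.00024, and adjusted p = 0.28 with an estimated correlation). Of 16 islet transcription factors 5 fell and 1 rose, with 6 and 1 adjusted over the list alone, led by falls of Myt1 at 2.37-fold and of Pax4, which was at least 1.12-fold lower, while St18, named after its values were seen, rose 1.45-fold (adjusted p = 0.0012, and adjusted p = 0.43 with an estimated correlation). Nkx6-1 fell by 0.60 ± 0.13. Of 11 endocrine progenitor genes 7 fell, also adjusted over the list alone, with the growth factor gene Mdk at least 4.35-fold and Gadd45a 2.76-fold lower (adjusted p = 0.00027, and adjusted p = 0.28 with an estimated correlation).

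In the same samples, again beside the acinar rise, of 60 oxidative phosphorylation genes 20 fell and 1 rose, with 18 and 1 adjusted over the list alone, led by Uqcrc1 at 1.84-fold and Atp5b at 1.78-fold lower, while Cox7b, named after its values were seen, rose 1.49-fold (median -0.21, adjusted p = 0.018, and adjusted p = 0.53 with an estimated correlation). Of 12 glycolysis genes 4 rose and 4 fell, with 5 and 4 adjusted over the list alone. The enolase gene Eno2 rose 8.15-fold and the phosphofructokinase gene Pfkl was 1.95-fold lower (median 0.04, which changed sign in 6 other settings, adjusted p = 0.0058, and adjusted p = 0.77 with an estimated correlation). Of 40 ribosomal protein genes 17 fell, 18 adjusted over the list alone, with Rplp0 2.01-fold and Rpl13a 1.87-fold lower (adjusted p = 0.0012, and adjusted p = 0.39 with an estimated correlation). Of 18 folding and stress genes of the endoplasmic reticulum 6 rose and 2 fell, also adjusted over the list alone, with Dnajb9 2.06-fold and the transcription factor gene Atf4 2.03-fold higher (adjusted p = 0.032, and adjusted p = 0.53 with an estimated correlation). Of 12 clock genes 6 rose and 2 fell, also adjusted over the list alone, with Nr1d2 1.86-fold and Dbp 2.02-fold higher (adjusted p = 0.039, and adjusted p = 0.54 with an estimated correlation). Of 11 G1 cyclins and inhibitors 3 rose and 3 fell, with 3 and 4 adjusted over the list alone. The inhibitor gene Cdkn1c, above background in 2 of 3 adult samples, was 6.04-fold lower and the cyclin gene Ccnd1 4.11-fold higher (adjusted p = 0.035, and adjusted p = 0.88 with an estimated correlation). The call of the oxidative phosphorylation list ended without adult replicate 2 or adult replicate 3, with adjusted p from 0.058 to 0.067. That of the endoplasmic reticulum list ended without any 1 of E18.5 replicates 1, 2 and 3 and adult replicates 2 and 3, from 0.059 to 0.15, and with median centring or the deposited values as log2. The clock list lost its call without any 1 of 9 samples (0.050 to 0.12, kept without E18.5 replicate 1, P1 replicate 1 or adult replicate 3), and with median centring or the deposited values as log2. The glycolysis call ended with median centring. The G1 list lost it without any 1 of E18.5 replicate 2, P1 replicates 1, 2 and 3, P10 replicates 1 and 2 and adult replicate 1 (0.050 to 0.22), and without background correction, with a normexp offset of 50, without a filter on dim probes and with the mean of a gene's probes. With only both ages fitted the calls of all these lists but the ribosomal list ended. With the acinar mean as an added term, 142 genes and 2 lists passed. Age accounted for 91.2% of the variance of that term, whose slope came from differences between samples of an age. Where acinar means lie apart, 5.36 at E18.5 against 10.1 in adults, age differences are estimated less precisely and shifted by that slope. A call lost with the term therefore need not mean that a difference was removed.

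Pooling both later ages against both earlier ages, 3563 genes passed, 1678 higher and 1885 lower. With median centring the split was 1247 higher and 2268 lower. Npy was 24.8-fold lower, Nnat 12.8-fold and Slc38a5 10.2-fold. Dlk1 (adjusted p = 1.6e-14) and Ghrl passed too, and since both were below background in every adult sample no fold is given. Npy and Nnat were above background in 4 of the 5 later samples. At the earlier ages Ctrl was so in 5 of 7 samples, Prss2 in 4 and Try10 in 6. Ucn3 rose by 3.01 ± 0.12 or 8.07-fold, Iapp 2.06-fold and G6pc2 2.04-fold, while Nkx6-1 fell by 0.64 ± 0.10. Try10 rose 48.7-fold, Ctrl 47.8-fold and Prss2 39.2-fold, and all 25 acinar markers rose. Of 26 lists tested 17 passed by fry. Of these the fetal growth and imprinted list had 11 genes falling and 1 rising of 12. It alone also passed by camera with an estimated correlation (adjusted p = 0.045). The cholesterol synthesis list passed here, with 5 genes rising and 1 falling of 16 (adjusted p = 0.036, and adjusted p = 0.55 with an estimated correlation). Its call ended without any 1 of E18.5 replicates 1, 2 and 3, P10 replicates 1 and 2 and adult replicates 1, 2 and 3, with adjusted p from 0.052 to 0.12, and with median centring or the deposited values as log2. With the acinar mean as an added term 92 genes and 2 lists passed.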

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

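The tests on acinar markers and those on ATF4 targets, except the check of scaling, were chosen after the results were seen, and the tests of chance splits, of scaling for ATF4 targets and of the clock were set before. When the test on the clock gene Arntl was set, it was known that 1 gene of the clock list fell adjusted over the list alone, but not which. Chance was argued against for the number of genes called between P1 and E18.5. There 1 of 35 splits of the 7 samples, the real one, gave as many as 502 genes and the highest other gave 47. The same held for adults against E18.5, with 3754 genes in 1 of 35 splits and 791 in the highest other. It also held for the pooled comparison, with 3563 genes in 1 of 100 drawn assignments and 919 in the highest other. No share under 1 of 35 or 1 of 100 could arise from these numbers of splits. Splits that mix the ages also move age differences into the spread, which lowers their counts, so chance is not excluded.

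Acinar marker transcripts rose from P1 to P10 and stayed high in adults, and the marker with the brightest probe, Pnliprp1, had a mean log2 level of 8.09 at E18.5, 12.98 at P10 and 11.77 in adults. Background correction or scaling was argued against, since the lowest median difference from P1 to P10 over 4 other treatments was 3.36. RNA of acinar cells carried into the samples in differing amounts may account for the pattern. Within an age, the markers' deviations had a mean pairwise correlation of 0.764. Sorting for fluorescence, however, would remove cells without the reporter. Expression of these genes by the sorted cells themselves cannot be told apart, because genes regulated together would correlate as well, and the standard deviation of 0.811 of the list's mean within an age excludes neither source. The age itself stays open, as untested.

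Targets of ATF4, a transcription factor of amino acid and endoplasmic reticulum stress, were listed after several had been seen to rise, and 22 of 36 measured rose from P10 to adults, 0 fell and 14 did not pass (median 0.73). Without the 8 genes seen first, 14 of 28 rose (fry p = 4.6e-06, p = 0.0021 with an estimated correlation, and fry p from 3.1e-06 to 8.6e-05 with each sample left out), and 3 of the listed genes are also in the endoplasmic reticulum list. The remaining 28 genes are targets of the same factor, measured in the same samples, so their p-values are not independent support. Some of them are also in other lists tested here. Acinar RNA of constant target levels was argued against by the whole list's median of -0.0958 from P1 to P10, where acinar markers rose most. At that step 3 targets rose and 6 fell. Acinar RNA whose target levels rose with age was not tested. Scaling was argued against by the lowest median of 0.499 over 4 other treatments. Handling stress that differed between ages cannot be told apart, as the immediate early list had a median of -0.345 and did not pass (adjusted p = 0.62). The age itself stays open, as untested.

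From E18.5 to P1, 5 of 12 circadian clock genes rose and 7 did not pass, with 7 rising and 1 falling adjusted over the list alone (list median 0.52, adjusted p = 0.041). The call ended with an estimated correlation (adjusted p = 0.32), with only both ages fitted (0.064), and without any 1 of 9 samples (0.057 to 0.13), namely E18.5 replicates 2, 3 and 4, P1 replicates 1, 2 and 3, P10 replicates 1 and 2 and adult replicate 1. Camera gave the value with an estimated correlation, and it compares the list with the other genes. Scaling was argued against as the whole cause by the lowest median of 0.301 over 4 other treatments. However, the call also ended with median centring (median 0.46, adjusted p = 0.098) and with the deposited values as log2 (0.41 and 0.056). Why the call ended was not tested. Sampling at another phase of the clock may contribute, since Arntl, which runs in antiphase and would then be lower, stood at -0.547 ± 0.17 (adjusted p = 0.070) and was the 1 clock gene that fell adjusted over the list alone. This explanation and the age cannot be told apart, because Arntl could be lower at P1 for either reason and no time of collection was used here. Arntl also did not pass over all genes.

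Among the 4 E18.5 samples, 26 of 323 measures had 1 sample far from the other 3, where chance gives about 1 in 20. Many measures share genes and all share the same 4 arrays, so no excess over chance is read from this. Replicate 4 was lowest in the mean of immediate early and heat shock genes at 8.14 (others 8.95 to 8.97), in islet transcription factors at 7.58 and in neural and Schwann cell markers at 5.65. It was also lowest in Nkx6-1 at 9.69, Jun at 8.02, Gap43 at 5.80, Pfkl at 8.60 and Ier3 at 7.37, and highest in Gpd1 at 5.59, Chac1 at 7.04 and Pbk at 8.80. Replicate 1 was lowest in G6pc2 at 10.35, Slc2a2 at 9.64, Chga at 11.29, Sqle at 8.55 and Pdia4 at 8.95. It was highest in Cpb1 at 5.84, Ngfr at 5.29, Cadps at 8.25, Gast at 6.46, Cox6c at 10.88 and Rora at 6.38. Replicate 2 was highest in Mdh2 at 9.50, Tcf19 at 7.64 and Gpr119 at 5.63, and lowest in Rpl35 at 11.24.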

How the results depend on the processing

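The added term for acinar markers was chosen after seeing the data, and the other alternatives were planned. Over named genes, 16160 recalculated values kept direction and side of the threshold, 776 no longer passed it, 266 newly passed it and 22 reversed; for lists, by the direction of the test, these were 2986, 316, 42 and 0. The median of a called list changed sign in 20 recalculations, 8 of which still passed. Of these, 13 were of glycolysis (medians from -0.081 to -0.0022), 3 of the G1 list, 2 of neuropeptides, and 1 each of cell cycle and antigen presentation, the last 2 with the acinar term; the cause was not tested. With median centring 5 lists passed for adults against P10, and without a filter on dim probes 2 lists for P1 against E18.5, where array weights gave 1010 genes; the cause was not tested. A minimum of 2-fold left 242 genes for P10 against P1, 51 for P1 against E18.5, 221 for adults against P10, 741 for adults against E18.5 and 376 for the pooled ages, by its construction. Replicate numbers were not taken to pair the samples. Same-number pairs correlated from -0.071 to 0.278 and 5 of 15 exceeded 0.1, against 6 of 38 pairs of other numbers. These values do not exclude a pairing by number, which stays open. With the replicate block, 217 genes and 0 lists passed for P1 against E18.5. That block also ended the calls of the clock and G1 lists for adults against E18.5, and of the cell cycle list for the pooled ages. The slide block was not run, because column names give no slide. Fitting only the ages compared gave 1 list for P10 against P1, 0 for adults against P10 and 12 for adults against E18.5. For P1 against E18.5 it gave 1 list, which was not called in the main fit. Each such fit used fewer samples. Camera with an estimated correlation left 0, 0, 0, 1 and 1 lists for P10 against P1, P1 against E18.5, adults against P10, adults against E18.5 and the pooled ages, and with a preset correlation 9 lists passed for P1 against E18.5 and 10 for the pooled ages. With the acinar term 52, 216, 142 and 92 genes passed for P10 against P1, P1 against E18.5, adults against E18.5 and the pooled ages, of which 50, 205, 141 and 90 were called without it, and 1286 genes by the F-test. The lists passing were 1, 0, 2 and 2. For adults against P10, whose acinar means of 10.1 and 9.79 lie close, 1109 genes passed, 1079 of them called without it, and 2 lists. The term was fitted beside the ages, so its slope came from differences between samples of an age. Age accounted for 91.2% of its variance. Where acinar means lie apart, age differences are therefore estimated less precisely and shifted by that slope. There a lost call need not mean that a difference was removed, and the term cannot separate the sources. All 22 reversals arose with it, none past the threshold. For P10 against P1 they were Try10 at -0.80, Ctrb1 at -0.40, Rnase1 at -0.0047 and Pnliprp1 at -0.52. For adults against E18.5 they were Try10 at -0.12, Amy2a5 at -0.32, Cela2a at -1.43, Try5 at -0.020, Pnliprp1 at -2.26, Me1 at -0.070 and Atp5b at 0.20. For the pooled ages they were Try10 at -0.46, Reg1 at -0.47, Top2a at 0.15, Pnliprp1 at -1.39, Lss at -0.0096, Tef at -0.12, St18 at -0.11, Laptm5 at 0.18, Got2 at 0.029, Atp5b at 0.092 and Cox4i1 at 0.045. Leaving out 1 sample gave from 392 to 1184 genes for P10 against P1, 114 to 600 for P1 against E18.5, 513 to 1293 for adults against P10, 3137 to 3723 for adults against E18.5, 2765 to 3514 for the pooled ages and 3506 to 3997 by the F-test. Lists called ranged from 1 to 9, 0 to 5, 1 to 7, 15 to 19 and 13 to 17 for the first 5 of these. Without a P10 replicate the remaining P10 sample is assumed to vary like the other ages. Signal over background limits dim genes, since between 40.0% and 48.3% of probes lay above background on an array.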

Other observations

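The counts of genes shared between steps, the levels per sample of the hormone genes and the levels of Rbm3 were looked at after the results were seen. Between E18.5 and adults, beside the rise of acinar markers, further lists fixed beforehand were tested. Of 18 genes of antigen presentation and interferon response 8 rose and 3 fell, with 9 and 3 adjusted over the list alone. Tap2, a peptide transporter for antigen presentation, rose 2.48-fold and the interferon-induced protease gene Usp18 2.11-fold (adjusted p = 0.00017, and adjusted p = 0.28 with an estimated correlation). Of 16 immediate early and heat shock genes 10 fell and 1 rose, also adjusted over the list alone. Zfp36, which promotes mRNA decay, was 7.64-fold lower, and the member that rose was the chaperone gene Hsph1, 2.71-fold (median -1.22, adjusted p = 0.033, and adjusted p = 0.53 with an estimated correlation). That call ended without any 1 of E18.5 replicates 1, 2 and 3, P1 replicate 1 and adult replicates 1 and 3, with adjusted p from 0.054 to 0.14. Of 8 neuropeptides and peptide hormones 4 fell and Ucn3 rose, also adjusted over the list alone, with Gal 3.25-fold lower (adjusted p = 0.0035, and adjusted p = 0.53 with an estimated correlation). The immediate early and neuropeptide calls also ended with only both ages fitted.

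In that comparison, of 11 markers of alpha, delta, PP and epsilon cells 5 fell and 1 rose, also adjusted over the list alone, led by Slc38a5 and Ghrl, while Etv1, named after its values were seen, was at least 1.15-fold higher (adjusted p = 0.0015, and adjusted p = 0.43 with an estimated correlation). Of 8 duct markers 6 fell and 0 rose, also adjusted over the list alone, led by the keratin gene Krt8 at 2.39-fold lower (median -0.64, adjusted p = 0.00017, and adjusted p = 0.28 with an estimated correlation). Of 10 endothelial markers 7 fell, also adjusted over the list alone, led by Egfl7 at 4.16-fold lower (adjusted p = 0.048, and adjusted p = 0.55 with an estimated correlation). The endothelial call ended without any 1 of 10 samples, with adjusted p from 0.054 to 0.12, and held without E18.5 replicate 1 or 4. It was lost in 18 of 26 settings in all, among them no background correction, a normexp offset of 50, the deposited values as log2, no filter on dim probes and the mean of a gene's probes. Of 14 mesenchyme markers 4 fell (adjusted p = 0.10 for the list), and of 8 leukocyte markers 2 fell (adjusted p = 0.30). Of 5 neural markers 2 fell and 1 rose (adjusted p = 0.37), and of 2 erythroid markers 1 fell, too few for a list test. This was Hba-a1 at -1.98 ± 0.61, above background in 2 of 3 adult samples, with an adjusted p of 0.089 without adult replicate 2. Of 26 citrate cycle genes 7 fell and 3 rose (adjusted p = 0.35), of 10 NADH shuttle genes 3 fell and 3 rose (adjusted p = 0.32), and of 16 cholesterol synthesis genes 3 fell and 2 rose (adjusted p = 0.35).

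Adult replicate 3 had lower levels of Gcg, Ppy and Pyy, hormone genes of other islet cells, than adult replicates 1 and 2. Gcg, which encodes glucagon, stood at 9.36 against 13.43 and 13.25, Ppy at 8.85 against 12.34 and 11.92, and Pyy at 10.16 against 12.53 and 12.60. The higher Gcg levels lie near the top of the array's range, where differences are hard to read. Rbm3 averaged 8.81 at E18.5, 10.06 at P1, 9.98 at P10 and 7.25 in adults.

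The steps from E18.5 to P1 and from P10 to adults share no samples, but the fit on all 12 samples gives both steps the same gene variances, and the counts for independent lists leave this out. Of the 238 genes that rose and the 264 that fell at the first step, 14 rose again at the second (14.4 for independent lists), 71 rose and then fell (17.6), 41 fell and then rose (16.02) and 81 fell at both (19.5). With each step fitted on its own samples, 230 genes rose and 250 fell at the first step. Of these, 11 rose at both (8.53), 45 rose and then fell (12.8), 30 fell and then rose (9.27) and 68 fell at both (13.9).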
